A study of Mus musculus with 16 samples.

How the data were processed

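RNA was measured in 16 tumours grown in mice from B16R2L, a mouse melanoma cell line. The cells carried either a non-targeting short hairpin RNA (shCtrl) or a hairpin against Mdk (shMdk), the gene of the secreted growth factor midkine. Once tumours reached 100 mm3, the mice received an antibody against the immune checkpoint receptor PD1 (clone RMP1-14) or an IgG2a control antibody, 2 times a week for 2 weeks, per the labels. The labels give a dose of 10 mg/kg for anti-PD1 and none for IgG2a. The summary of the design gives the same number for anti-PD1 in grams per kg, and the unit of the labels is the one quoted here. The 4 combinations of hairpin and antibody had 4 tumours each. Replicate numbers within a group were given here in accession order, so they only name a tumour and pair nothing. The labels describe the samples of a group as separate tumours, so p-values of single genes and of permutation tests are set against the spread between tumours.

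Libraries were made from 500 ng of total RNA, with RNA integrity numbers of 8.6 on average (range 5.8 to 9.2), using a stranded kit that primes on the poly(A) tail and reads the 3′ end of transcripts, and were sequenced on a NextSeq 550, per the labels' protocols. Such reads count transcripts by their 3′ ends, so gene length does not scale the values. A gene whose 3′ end is poorly annotated or hard to amplify is undercounted. Per the submitters' processing notes, the tools were FastQC 0.11.0, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19, HTSeq and DESeq2, with the mouse genome build GRCm38 (mm10). The labels' protocols give strand-specific settings for alignment and counting, so antisense genes were counted apart from their partners.

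The deposited table holds 1 normalised signal per gene and tumour, which the authors made by dividing read counts by DESeq2 size factors, per the submitters' processing notes and the values themselves. Whole reads could be recovered from these values: 100% of them were whole multiples of the value of 1 read within 0.001, and size factors recomputed from the recovered reads equalled the deposited ones within 1e-06 in 16 of 16 tumours. The recovered totals ran from 5686405 to 8886334 reads per tumour. The table listed 16094 genes. Columns of per-sample values left unused numbered 0. Multigene families with near-identical members, among them H2-Q6 and H2-Q7, the granzymes Gzmc to Gzmg, the Ly6c genes, the guanylate-binding proteins, Tgtp1 and the immunoglobulin genes, can share reads, and their values are uncertain for that reason.

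The main test was limma 3.58.1 in R 4.3.3 (linear model with group means, moderated variances with a trend on expression) on log2(normalised count + 1), with all 16 tumours in the fit and 12 residual degrees of freedom. Genes with a mean normalised count of at least 5 were kept, which left 14672. Calls used a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and every adjusted p in the text comes from this procedure unless another tool is named. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 5 comparisons were anti-PD1 against IgG2a within shCtrl and within shMdk tumours, shMdk against shCtrl within each antibody, and the difference between the anti-PD1 effects of the lines, which was the only test used to call effects different. Errors beside means are standard deviations over tumours, and errors beside log2 fold changes are standard errors of the fit. Single values were compared with two-sided exact permutation tests, which for 4 against 4 tumours cannot give a p under 0.0286. The design of each test, the gene lists, the rule for named genes and the settings varied in advance were set before the data were examined.

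Named genes were chosen per comparison by a rule. It took Mdk, then up to 10 genes with the largest rise and 10 with the largest fall among those that passed, showed no overlap between the groups and had a symbol that is not a Gm, Rik or pseudogene model. Where no gene passed, it took the 5 genes with the smallest p. It added up to 4 passing members of each called list, or else 2 with the largest change that did not pass, and a fixed set (among them Cd8a, Cd274, Cxcl9, H2-K1, B2m, Arg1, Adgre1, Tyr and Mki67). Gzmb, Ifng and Foxp3 were also in that set. Gzmb and Ifng had no entry in the table used, and Foxp3 lay below the expression filter. The cytotoxic list was therefore tested on 10 of 18 members, without Gzmb and Ifng, and interferon gamma itself was not measured here, only genes that respond to it. The text gives the genes that matter most among those the rule names.

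Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 31 lists within a comparison. Camera compares the genes of a list with all other genes. Its p-values therefore depend on the number of genes and on that preset correlation, and do not measure the spread between tumours alone. Where members of a list vary together more than preset, these p-values are too small. They were type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, T cell, cytotoxic effector, immune checkpoint and exhaustion, regulatory T cell, NK cell, B and plasma cell, macrophage and monocyte, alternatively activated myeloid, dendritic cell, neutrophil, chemokines, NF-kB targets, melanocyte pigmentation, dedifferentiated melanoma state, cell cycle, hypoxia and glycolysis, unfolded protein and integrated stress, immediate early and heat shock, mitochondrially encoded, fibroblast and extracellular matrix, blood endothelium, lymphatic endothelium, skeletal muscle, keratinocyte, adipocyte, erythroid, and midkine partners. Some tested genes stand in more than 1 list: 6 of 18 chemokines, 5 of 26 interferon gamma genes, 3 of 10 cytotoxic genes, 3 of 20 NF-kB targets and 2 of 3 NK cell genes. A list score is the mean, over members, of each tumour's log2 value minus the gene's mean over all tumours.

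Settings fixed in advance were pseudocounts of 0.5 and 5, no filter and a filter at a mean of 20, TMM factors, quantile normalisation, limma sample weights, robust variance moderation, fits of only the compared groups, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation, limma's fry, and leaving out each tumour in turn. Alternatives added after seeing the data were 2 surrogate variables (sva 3.50.0), a per-library correction on the GC content of the last 100 nucleotides of transcripts, and fits without 2 or without 5 libraries that stood apart. GC values came from GENCODE M21 annotation and sequence (GRCm38) for 14590 tested genes (99.4%). Gene coordinates are 1-based from the same annotation, in which 16029 symbols were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

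The procedure was tested on simulated reads drawn from the real means, library sizes and dispersions, with 200 genes changed. Genes were drawn independently, so the simulation held no variation shared between genes, which the real tumours did show. Recovery and false calls in the real data can therefore differ from these values. For knockdown under IgG2a (14509 genes tested) it recovered 32.8% of genes changed 2-fold, 76.1% of those changed 4-fold and 93.9% of those changed 8-fold, with 12 false calls. For knockdown under anti-PD1 (14501 genes) these shares were 35.8%, 83.6% and 93.9%, with 8 false calls. For anti-PD1 they were 43.3%, 73.1% and 95.5% in shCtrl tumours (14488 genes, 11 false calls) and 40.3%, 71.6% and 90.9% in shMdk tumours (14523 genes, 5 false calls). The test of the difference recovered 10.4% of 2-fold, 55.2% of 4-fold and 81.8% of 8-fold differences (14517 genes, 8 false calls).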

Results

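Gene expression was measured in 16 B16R2L melanoma tumours from mice, in 4 groups of 4: control-hairpin (shCtrl) or Mdk-hairpin (shMdk) tumours, each under an IgG2a control antibody or an antibody against PD1. The series title names the response of Mdk-knockdown tumours to PD1 therapy as its subject. Recovered reads ranged from 5686405 (shCtrl anti-PD1 tumour 2) to 8886334 (shMdk anti-PD1 tumour 3) per tumour, and 15508 to 16014 genes had at least 1 read. Within groups, log2 values of tumour pairs correlated across genes at r = 0.907 to 0.982, and genes are not independent replicates. All pairs within a group differed by more than counting error alone, with a smallest chi-square per degree of freedom of 8.27. The tumours were treated as separate samples because the labels describe them so. Gm42418, a gene model that overlaps ribosomal RNA sequence, took 4.47% of reads in shCtrl anti-PD1 tumour 2 and 3.17% in shMdk IgG2a tumour 1, against 0.880% to 1.56% in the rest. In 5 tumours, genes with GC-rich 3′ ends read higher. The slope was 0.21 and 0.14 log2 units per 10% GC in shCtrl IgG2a tumours 1 and 2, 0.09 and 0.24 in shMdk IgG2a tumours 3 and 4, and 0.11 in shMdk anti-PD1 tumour 1. In the rest it was -0.14 to -0.01. These slopes are averages over genes, and single genes could differ far more. Ctnnd1, an example, had 7.88, 28.8, 36.0, 9.46 and 46.6 normalised reads in these 5 tumours, in the same order. In the rest it had 186 to 954. Each main count is also given without these 2 or these 5 libraries, which were chosen after the data were seen.

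Mdk itself (ENSMUSG00000027239.14, chromosome 2, 91929805 to 91932297, minus strand, GRCm38) was lower in all 8 shMdk tumours than in any shCtrl tumour under the same antibody. Its normalised read counts were 601, 727, 959 and 1161 in shCtrl IgG2a tumours and 150, 203, 323 and 121 in shMdk IgG2a tumours. Under anti-PD1 they were 925, 606.5, 1104 and 855.5 in shCtrl and 312, 290, 147 and 96.5 in shMdk tumours. Means fell from 862 ± 249 to 199 ± 89.3 under IgG2a and from 873 ± 206 to 211 ± 106 under anti-PD1 (SD, n = 4). The log2 fold changes of the model were -2.16 ± 0.36 (SE, limma adjusted p = 0.00428) and -2.17 ± 0.36 (adjusted p = 0.00166), which correspond to 22.3% of control in both arms. Exact permutation tests gave p = 0.0286 in each arm, the smallest that 70 arrangements allow. Anti-PD1 moved Mdk by 0.03 ± 0.36 in shCtrl and 0.03 ± 0.36 in shMdk tumours (adjusted p = 0.987 and 0.981).

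**Figure D1:**
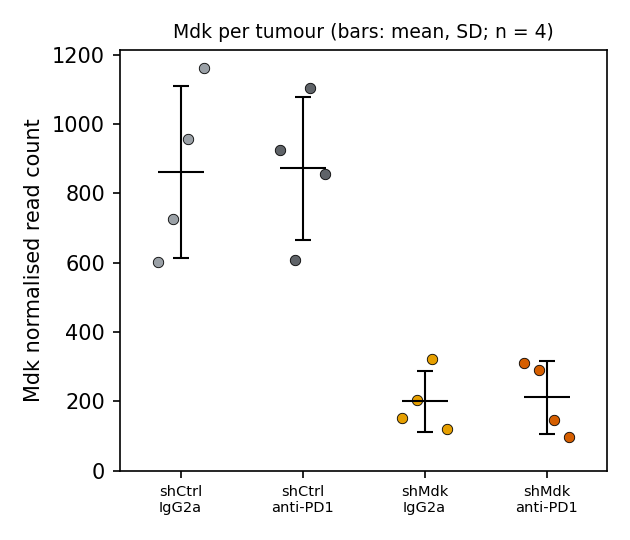
Mdk normalised read count (vertical axis) in each of the 16 tumours, by hairpin and antibody (horizontal axis), with bars for the mean and SD of 4 tumours. The shMdk tumours lie between 96.5 and 323, below the shCtrl tumours, which lie between 601 and 1161.

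The difference between shMdk and shCtrl tumours without PD1 blockade was tested under IgG2a. Each line carried 1 hairpin, so for every gene and list in the knockdown comparisons a difference between the lines cannot be separated from the loss of Mdk. Genes of antigen presentation, of the response to interferon gamma (the main T cell and NK cell cytokine acting on tumours) and of immune cells rose in shMdk tumours. Cd74, the invariant chain of MHC class II, rose from 166 ± 152 to 2061 ± 788 normalised reads (SD, n = 4; log2 fold change 3.92 ± 0.70, adjusted p = 0.00614). The interferon-induced GTPase gene Gbp4 rose from 6.77 ± 3.48 to 216 ± 128 (4.76 ± 0.70, adjusted p = 0.00215), and Gzmc, a granzyme of cytotoxic lymphocytes, from 2.42 ± 2.89 to 65 ± 45.8 (4.36 ± 0.63, adjusted p = 0.00208).

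Of 26 interferon gamma response genes tested, 17 rose and 0 fell, 9 did not pass, and 21 rose adjusted over the list alone. The mean log2 fold change of the list was 2.26. Iigp1, a GTPase acting against intracellular parasites, rose by 3.40 ± 0.54 and the T cell attracting chemokine gene Cxcl9 by 3.78 ± 0.75 on the log2 scale. All 9 MHC class II genes rose (9 adjusted over the list alone; mean 3.07), among them H2-Eb1 by 3.89 ± 0.67 and H2-Ab1 by 3.50 ± 0.60, which encode antigen-presenting chains. For MHC class I presentation, 7 of 19 rose (14 adjusted over the list alone; mean 1.12), including the immunoproteasome subunit genes Psmb8 (2.01 ± 0.36) and Psmb10 (1.70 ± 0.30), while H2-K1 missed the threshold at 1.09 ± 0.27 (adjusted p = 0.0503). Macrophage and monocyte genes rose in 11 of 21 cases (19 adjusted over the list alone; mean 2.04), such as Ly6c2, a surface protein of inflammatory monocytes, by 2.84 ± 0.55. Cytotoxic effector genes rose in 5 of 10 (10 adjusted over the list alone; mean 2.98), with Nkg7, a cytotoxic granule protein, at 27.7 ± 3.37 against 2.42 ± 2.89 reads. Gzma, a granzyme, rose from 1 read over the shCtrl group to 67 over the shMdk group, and no fold is given for it.

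Type I interferon response genes rose in 8 of 30 (14 adjusted over the list alone; mean 0.90; adjusted p = 0.0613 with an estimated correlation), among them Oas3, a sensor enzyme for double-stranded RNA, by 2.55 ± 0.39. Chemokine genes rose in 2 of 18 (11 adjusted over the list alone), Cxcl9 and Ccl4. NK cell genes rose in 2 of 3 (3 adjusted over the list alone). NF-kB targets rose in 2 of 20 (2 adjusted over the list alone), which were the leukocyte adhesion molecules Icam1 and Vcam1, and checkpoint genes in 2 of 10 (3 adjusted over the list alone). B and plasma cell genes rose in 2 of 8 (3 adjusted over the list alone; adjusted p = 0.0507 with an estimated correlation), namely the light-chain gene Igkc and Cd22. The calls of Icam1, Vcam1, Igkc and Cd22 were each lost in 6 of 8 fits that left out a tumour. The T cell list was higher as a list (mean 1.37, camera adjusted p = 2.64e-07), with 0 of 16 members passing over all genes, 5 adjusted over the list alone, and Trbc2 at 2.85 ± 0.84 (adjusted p = 0.120). Cd8a was at 9.59 ± 7.30 against 1.02 ± 1.19 reads (adjusted p = 0.223). Alternatively activated myeloid genes had a mean of 0.67 with 0 of 12 passing (adjusted p = 0.165 with an estimated correlation). Dendritic cell genes had a mean of 0.64 and 1 of 8 passing, Itgax (2.94 ± 0.48; list adjusted p = 0.206 with an estimated correlation). Lists that were lower were cell cycle (mean -0.21, 0 of 28 passing; adjusted p = 0.501 with an estimated correlation) and unfolded protein and integrated stress (mean -0.19, 0 of 17 passing; adjusted p = 0.349 with an estimated correlation). The dendritic cell call was lost without shCtrl IgG2a tumour 1, 3 or 4 (adjusted p = 0.0631, 0.0573 and 0.0563) or shMdk IgG2a tumour 2, 3 or 4 (0.0543, 0.0924 and 0.0689). The stress call was lost without shCtrl IgG2a tumour 1 or 2 (0.0996 and 0.136) or shMdk IgG2a tumour 1 or 3 (0.326 and 0.0652). Without the 2 libraries high in Gm42418 the stress call ended (0.337), and without the 5 with a positive GC slope both did (dendritic cell 0.0901, stress 0.0934). Leaving out a tumour moved the mean to between -0.38 and -0.10 for cell cycle and -0.25 and -0.12 for stress genes. Median, mean and test differed in sign for the neutrophil, dedifferentiated melanoma, keratinocyte and midkine partner lists, none of them called.

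Over all 14672 genes, 255 passed under IgG2a, 239 higher and 16 lower in shMdk tumours, and 227 of them differed at least 2-fold. Genes that fell included Ano3, an anoctamin membrane protein, from 614 ± 81.4 to 346 ± 34 (log2 fold change -0.82 ± 0.15, adjusted p = 0.00614). Grb7, a signalling adaptor, fell from 32.8 ± 10.8 to 4.29 ± 3.61 (-3.02 ± 0.54, adjusted p = 0.00614) and Acsbg1, an acyl-CoA synthetase, from 400 ± 21.8 to 185 ± 51.7 (-1.15 ± 0.22, adjusted p = 0.00963). Ighg2c, an antibody heavy-chain gene, rose from 1.29 ± 0.962 to 59.7 ± 30.5 (4.69 ± 0.56, adjusted p = 5.60e-04). The antisense RNA gene Peak1os had 0 reads in the shCtrl group and 14.9 ± 6.93 normalised reads in shMdk tumours, at least 19.6-fold higher against a floor of 3 counts over the group (adjusted p = 0.00144). The groups did not overlap for 894 genes (6.09%), against 2.86% by chance, and 1422 genes had an unadjusted p under 0.05. The count was 160 and 158 without shCtrl IgG2a tumour 3 or 4, and 167 and 136 without shMdk IgG2a tumour 1 or 3. Lower genes numbered 7 and 9 without shCtrl IgG2a tumours 3 and 4, and 10 without shMdk IgG2a tumour 3. Without the 2 libraries high in Gm42418 it was 263, and without the 5 with a positive GC slope 74 (47 higher, 27 lower), 48 of them among the 255. With all tumours, edgeR gave 251 genes and DESeq2 449.

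Removing these 5 libraries left 2 tumours in each IgG2a group. Of 47 named genes that passed, 34 lost their calls without these libraries. In the genes given next, log2 fold changes stayed similar while standard errors grew. Gbp4 went from 4.76 ± 0.70 to 4.99 ± 1.06 (adjusted p = 0.0582), Iigp1 from 3.40 ± 0.54 to 3.67 ± 0.79 (0.0635), Cd74 from 3.92 ± 0.70 to 4.31 ± 0.96 (0.0651) and H2-Eb1 from 3.89 ± 0.67 to 4.33 ± 0.93 (0.0608). H2-Ab1 went from 3.50 ± 0.60 to 3.83 ± 0.85 (0.0655), Ly6c2 from 2.84 ± 0.55 to 3.21 ± 0.79 (0.0883), Nkg7 from 3.36 ± 0.63 to 3.81 ± 0.94 (0.0891) and Cxcl9 from 3.78 ± 0.75 to 4.18 ± 1.04 (0.0917). Oas3 went from 2.55 ± 0.39 to 2.31 ± 0.48 (0.0556), Itgax from 2.94 ± 0.48 to 3.00 ± 0.75 (0.0917) and Acsbg1 from -1.15 ± 0.22 to -1.24 ± 0.29 (0.0738). Gzma, Igkc, Icam1, Vcam1, Cd22 and Ccl4 also lost their calls (adjusted p = 0.251, 0.125, 0.183, 0.120, 0.126 and 0.083). Gzmc, Psmb8, Psmb10, Ano3, Grb7 and Ighg2c still passed, and Peak1os fell below the expression filter. Grb7 moved from -3.02 ± 0.54 to -4.08 ± 0.74. Leaving out as many tumours of each group in 143 other ways gave 1 to 1990 genes (median 2), with 74 or fewer in 121 of them. Most of these left tumours with and without a positive GC slope mixed within a group. They therefore cannot tell smaller groups apart from the GC trend.

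The same comparison was made between treated tumours, under anti-PD1. Cytotoxic, myeloid, chemokine and antigen-presentation genes rose in shMdk tumours. Gzmc rose from 2.73 ± 3.195 to 169 ± 82.7 normalised reads (SD, n = 4; log2 fold change 5.82 ± 0.63, adjusted p = 7.76e-05) and Prf1, the pore-forming protein of killer cells, from 1.38 ± 1.20 to 44.7 ± 16.5 (4.35 ± 0.69, adjusted p = 0.00136). Arg1, an arginine-degrading enzyme of myeloid cells, rose from 52.3 ± 60 to 730.4 ± 177 (4.31 ± 0.60, adjusted p = 6.26e-04). The chemokine gene Ccl8 rose from 150 ± 128 to 2189 ± 1015 (4.34 ± 0.64, adjusted p = 9.34e-04). H2-K1, a classical MHC class I heavy chain, rose from 3387 ± 1361 to 8674 ± 1036 (1.48 ± 0.27, adjusted p = 0.00316).

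Interferon gamma response genes rose in 19 of 26 (23 adjusted over the list alone; mean log2 fold change 2.36), with Cxcl9 at 714 ± 182 against 63.4 ± 53.3 reads (4.19 ± 0.75) and Gbp5 up by 3.77 ± 0.66. Macrophage and monocyte genes rose in 18 of 21 (21 adjusted over the list alone; mean 2.55), such as Ly6c2 (4.12 ± 0.55) and the monocyte chemokine receptor Ccr2 (3.73 ± 0.64). All 9 MHC class II genes rose (9 adjusted over the list alone; mean 2.89), as did 10 of 19 class I genes (14 adjusted over the list alone; mean 1.19), including the peptide transporter Tap1 (1.66 ± 0.28). Chemokine genes rose in 14 of 18 (15 adjusted over the list alone; mean 2.45), with Cxcl16 up by 3.76 ± 0.67. Cytotoxic genes rose in 9 of 10 (9 adjusted over the list alone; mean 3.67) and type I interferon genes in 15 of 30 (22 adjusted over the list alone; mean 1.27). Alternatively activated myeloid genes rose in 9 of 12 (10 adjusted over the list alone; mean 2.55), such as the chitinase-like Chil3 (4.36 ± 0.66) and the lectin Mgl2 (3.90 ± 0.63). T cell genes rose in 6 of 16 (12 adjusted over the list alone; mean 2.00), with Cd3d, a chain of the T cell receptor complex, at 29.9 ± 15 against 2.04 ± 2.87 reads (3.61 ± 0.58), while Cd8a was at 12.1 ± 8.58 against 1.83 ± 1.67 (adjusted p = 0.1497).

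NF-kB targets rose in 7 of 20 (12 adjusted over the list alone), such as the co-stimulatory receptor Cd40 (3.69 ± 0.54), and NK cell genes in 3 of 3 (3 adjusted over the list alone). Checkpoint genes rose in 4 of 10 (6 adjusted over the list alone), such as Pdcd1lg2, a ligand of PD1 (3.61 ± 0.66), and neutrophil genes in 4 of 13 (5 adjusted over the list alone). Cd274, the other PD1 ligand, had a log2 fold change of 1.42 ± 0.45 (adjusted p = 0.0760). Dedifferentiated melanoma genes rose in 4 of 15 (4 adjusted over the list alone), among them the receptor kinase Axl (1.90 ± 0.30), and Tgfbi and Tnc, which act in the extracellular matrix. Fibroblast and matrix genes rose in 10 of 18 (15 adjusted over the list alone; mean 1.58; adjusted p = 0.0813 with an estimated correlation), such as the collagen gene Col1a1 (2.13 ± 0.53). Blood endothelium rose in 3 of 14 (4 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation), such as the endothelial receptor Tie1 (1.55 ± 0.32). B and plasma cell genes rose in 3 of 8 (4 adjusted over the list alone; adjusted p = 0.0809 with an estimated correlation) and dendritic cell genes in 2 of 8 (2 adjusted over the list alone; adjusted p = 0.0809 with an estimated correlation). Midkine partners rose in 2 of 11 (3 adjusted over the list alone; adjusted p = 0.1797 with an estimated correlation), the heparan sulphate proteoglycan Sdc3 (1.61 ± 0.20) and Lrp1, an endocytic receptor (1.04 ± 0.29). Immediate early and heat shock genes rose in 2 of 15 (3 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation), and that list lost its call without shCtrl anti-PD1 tumour 3 (adjusted p = 0.0575) or shMdk anti-PD1 tumour 4 (adjusted p = 0.324; mean 0.18, against 0.51). Cell cycle was lower as a list (mean -0.30, -0.42 to -0.18 when a tumour was left out, 0 of 28 passing; adjusted p = 0.276 with an estimated correlation), with Mki67, a proliferation marker, at -0.14 ± 0.20 (adjusted p = 0.788). Median, mean and test differed in sign for the hypoxia and adipocyte lists, neither of them called.

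Over all genes, 870 passed under anti-PD1, 724 higher and 146 lower in shMdk tumours, with 655 at least 2-fold. Ippk, an inositol phosphate kinase, fell from 201 ± 97 to 63.5 ± 16.3 (log2 fold change -1.57 ± 0.30, adjusted p = 0.00425) and Dhrs2, a dehydrogenase, from 267 ± 120 to 97.1 ± 23.7 (-1.38 ± 0.25, adjusted p = 0.00320). Myc, the proto-oncogene transcription factor, fell from 74.9 ± 18.8 to 26 ± 10.7 (-1.54 ± 0.41, adjusted p = 0.0323), a call lost in 7 of 8 fits that left out a tumour. Gzmg, a granzyme, had 0 reads in the shCtrl group and 75.1 ± 74.6 in shMdk tumours, at least 98.7-fold higher against a floor of 3 counts over the group (adjusted p = 0.00194). Without shMdk anti-PD1 tumour 1 this bound was 52.1-fold. Granzymes Gzmc to Gzmg are near-identical copies and can share reads. The groups did not overlap for 1970 genes (13.4%, against 2.86% by chance), and 2617 genes had an unadjusted p under 0.05. Without shMdk anti-PD1 tumour 1 the count was 443 and without tumour 2 it was 569. Lower genes numbered 49 and 82 in these fits, and 73, 80 and 54 without shCtrl anti-PD1 tumours 1, 3 and 4. Leaving out the 2 libraries high in Gm42418 gave 953, and leaving out the 5 with a positive GC slope gave 621, with 519 of them among the 870. With 4 shCtrl and 3 shMdk tumours left there, Col1a1 (2.13 ± 0.53 to 1.61 ± 0.50, adjusted p = 0.0964), Tnc (2.70 ± 0.55 to 2.31 ± 0.60, 0.0508) and Lrp1 (1.04 ± 0.29 to 0.96 ± 0.30, 0.102) then did not pass. Removing as many tumours in other ways gave 209 to 1154 genes (median 505). The Col1a1 and Lrp1 calls were also lost in 5 and 6 of 8 fits that left out a tumour. With all tumours, edgeR gave 866 genes and DESeq2 1310.

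Across all 14672 genes the knockdown effects under IgG2a and under anti-PD1 correlated at r = 0.62 (Spearman rho 0.452), with genes not being independent replicates and no library shared between the comparisons. Of the 239 genes higher under IgG2a and the 724 higher under anti-PD1, 214 were the same genes, against 11.8 for independent lists. For lower genes the overlap was 6, against 0.159. Both comparisons came from 1 fit with a shared variance per gene. Some overlap beyond that of independent lists can therefore arise without a shared effect. All 255 genes that passed under IgG2a had the same sign under anti-PD1. The gene model Gm43305 (ENSMUSG00000105703.2, chromosome 14, 54292443 to 54297456), named here after its values were seen, had the smallest adjusted p in both, with log2 fold changes of 6.33 ± 0.23 (adjusted p = 1.72e-11) and 5.55 ± 0.23 (adjusted p = 1.56e-10).

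**Figure D2:**
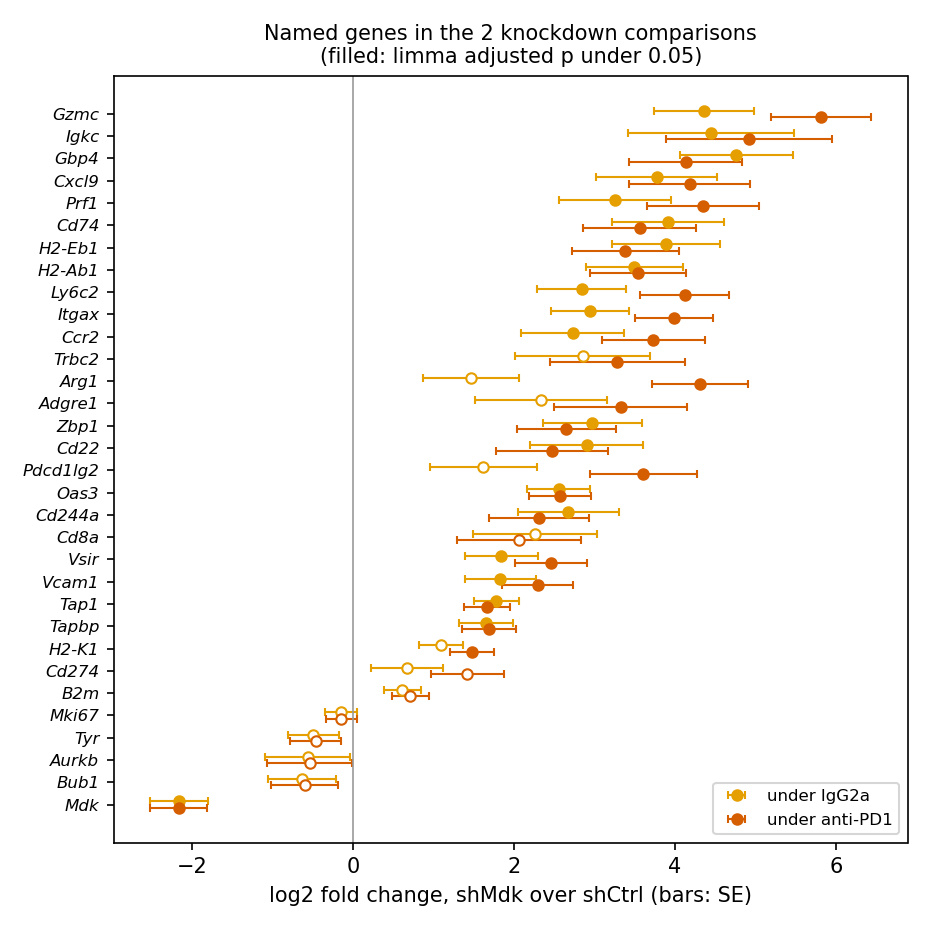
Log2 fold change of shMdk over shCtrl tumours (horizontal axis, bars: standard error) for named genes (vertical axis) under IgG2a and under anti-PD1, with filled points for limma adjusted p under 0.05. Gbp4 is highest under IgG2a (4.76), Gzmc under anti-PD1 (5.82), and Mdk lowest at -2.16 and -2.17.

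The effect of anti-PD1 alone was tested in shCtrl tumours, where 0 of 14672 genes passed with limma. The gene with the smallest p, C130026I21Rik, was at 56.4 ± 28.7 against 12 ± 1.89 normalised reads (SD, n = 4; log2 fold change 2.02 ± 0.33, adjusted p = 0.141). Sdc3 was at 116 ± 20.3 against 59.4 ± 10.9 (0.95 ± 0.20), Rapgef5, a guanine nucleotide exchange factor, at 41.2 ± 6.84 against 18.6 ± 2.59 (1.10 ± 0.23) and Abcg3, a membrane transporter, at 18.6 ± 9.49 against 2.62 ± 2.73 (2.62 ± 0.56), each with an adjusted p of 0.578. Cd274 was at 93.4 ± 31.5 against 162 ± 138 (adjusted p = 0.798).

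Gene lists that were higher in anti-PD1 treated shCtrl tumours were MHC class I (mean log2 fold change 0.61, camera adjusted p = 2.00e-06; adjusted p = 0.578 with an estimated correlation), with 3 of 19 passing adjusted over the list alone. Higher too were interferon gamma response (0.66, adjusted p = 1.12e-05; adjusted p = 0.860 with an estimated correlation) and MHC class II (0.85, adjusted p = 2.95e-04; adjusted p = 0.860 with an estimated correlation). Higher values were also called for macrophage and monocyte (0.40), type I interferon (0.21) and adipocyte genes (0.69, with 1 of 4 adjusted over the list alone), and lower values for fibroblast and matrix (-0.43) and stress genes (-0.17). Their adjusted p was 0.578 with an estimated correlation for adipocyte and 0.860 for the others. No member of the 8 lists passed over all genes: Psmb9, an immunoproteasome subunit, was at 1.61 ± 0.52, H2-Aa at 1.27 ± 0.48, Gbp4 at 1.82 ± 0.70 and Col3a1, a collagen, at -0.95 ± 0.74 (adjusted p = 0.798 each). The fibroblast call was lost without shCtrl anti-PD1 tumour 2 (adjusted p = 0.232) and without both libraries high in Gm42418 (0.282), and the adipocyte call without the 5 with a positive GC slope (0.112). MHC class I kept its call in every fit that left out a tumour. Means ran from 0.33 to 1.14 for interferon gamma, 0.50 to 1.35 for MHC class II, 0.14 to 0.87 for macrophage and -0.68 to -0.15 for fibroblast genes in these fits. The interferon gamma call was lost without anti-PD1 tumour 3 or 4 (adjusted p = 0.0915 and 0.0580), the MHC class II call without those or IgG2a tumour 4 (0.0590, 0.0676 and 0.0872). The fibroblast call was also lost without IgG2a tumour 4 or anti-PD1 tumour 4 (0.294 and 0.0580). The macrophage call was lost without IgG2a tumour 3 or 4 (0.353 and 0.357) or anti-PD1 tumour 3 or 4 (0.501 and 0.497). Type I interferon, stress and adipocyte calls were lost without IgG2a tumour 2, 3 or 4 or anti-PD1 tumour 1, 3 or 4 (adjusted p = 0.0580 to 0.791), and the type I interferon mean turned to -0.03 without anti-PD1 tumour 3. Median, mean and test differed in sign for 8 uncalled lists: checkpoint, regulatory T cell, alternatively activated myeloid, neutrophil, dedifferentiated melanoma, cell cycle, mitochondrially encoded and skeletal muscle.

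At an unadjusted p under 0.05 there were 556 genes in shCtrl tumours, against 733.6 expected with no effect, and 1367 and 1378 without IgG2a tumour 3 or 4, 291 without tumour 1 and 341 without tumour 2. Sample weights gave 833. Groups did not overlap for 310 genes (2.11%, against 2.86% by chance). edgeR gave 0 genes and DESeq2 7. Without shCtrl anti-PD1 tumour 2 limma gave 2 genes, without the 2 libraries high in Gm42418 3, and without the 5 with a positive GC slope 0. Removing as many tumours per group as these 5, in 143 other ways, gave 0 genes in 124 and up to 2162. All counts above 0 came without shCtrl IgG2a tumours 3 and 4 together. That left IgG2a tumours 1 and 2, both with a positive GC slope, against anti-PD1 tumours without one. The number of lists called was 15, 5, 4 and 2 without IgG2a tumours 1, 2, 3 and 4, and 5, 15, 2 and 1 without anti-PD1 tumours 1, 2, 3 and 4.

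In shMdk tumours, anti-PD1 raised 4 genes and lowered 1. Ctsl, the lysosomal protease cathepsin L, rose from 479 ± 33.4 to 1269 ± 241 normalised reads (SD, n = 4; log2 fold change 1.39 ± 0.19, adjusted p = 0.0152) and Sdc3 from 138 ± 36.1 to 352 ± 29 (1.38 ± 0.20, adjusted p = 0.0152). Mmp12, the macrophage elastase, rose from 169 ± 60.9 to 660 ± 162 (1.99 ± 0.31, adjusted p = 0.0312) and Slfn4, a Schlafen family gene of myeloid cells, from 10.7 ± 5.28 to 65.3 ± 6.75 (2.60 ± 0.44, adjusted p = 0.0481). Mbnl3, a regulator of RNA splicing, fell from 244 ± 6.57 to 119 ± 17 (-1.04 ± 0.18, adjusted p = 0.0481). Of 8 fits that left out a tumour, Slfn4 lost its call in 8, Mbnl3 in 7, and Ctsl, Sdc3 and Mmp12 in 5 each. Of all 23 alternatives the calls were lost in 16 for Slfn4, 13 for Mbnl3, 7 for Mmp12, 6 for Sdc3 and 5 for Ctsl. Without shMdk IgG2a tumours 1, 2, 3 and 4 the count was 3, 0, 0 and 0, and without shMdk anti-PD1 tumours 1, 2, 3 and 4 it was 3, 0, 12 and 0. With TMM factors 3 rose and 0 fell, and leaving out the 2 libraries high in Gm42418 gave 11. Leaving out the 5 with a positive GC slope, with 2 IgG2a and 3 anti-PD1 tumours left, kept the call of Ctsl alone (1 gene). The others became 1.96 ± 0.42 for Mmp12, 2.46 ± 0.62 for Slfn4 and -0.98 ± 0.20 for Mbnl3 (adjusted p = 0.242 each) and 1.14 ± 0.22 for Sdc3 (0.239). Removing as many tumours in 143 other ways gave 0 to 1279 genes (median 0), and 1 or fewer in 132 of them. The groups did not overlap for 1249 genes (8.51%, against 2.86% by chance), and 1826 genes had an unadjusted p under 0.05, 1206 without IgG2a tumour 4 and 1166 without anti-PD1 tumour 4. edgeR gave 8 genes and DESeq2 248.

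All 19 lists called in shMdk tumours were higher under anti-PD1. Alternatively activated myeloid genes had the largest mean log2 fold change (1.85, camera adjusted p = 6.83e-10; adjusted p = 0.0256 with an estimated correlation), with 0 of 12 passing over all genes and 9 adjusted over the list alone. Arg1 was at 730.4 ± 177 against 142 ± 66.3 reads (2.44 ± 0.60, adjusted p = 0.162) and Chil3 at 103 ± 70.6 against 12.3 ± 9.25 (3.08 ± 0.66, adjusted p = 0.112). Chemokines (mean 1.37, adjusted p = 6.28e-09; adjusted p = 0.0414 with an estimated correlation; 9 of 18 adjusted over the list alone), NF-kB targets (0.67, adjusted p = 1.52e-05; adjusted p = 0.00894 with an estimated correlation; 3 of 20 adjusted over the list alone) and dedifferentiated melanoma genes (0.92, adjusted p = 1.10e-04; adjusted p = 0.0414 with an estimated correlation; 2 of 15 adjusted over the list alone) also kept their calls. The monocyte chemokine gene Ccl2 was at 224 ± 89.4 against 50.4 ± 15.1 (2.09 ± 0.47, adjusted p = 0.121).

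The other 15 lists lost their calls with an estimated correlation, in brackets as that adjusted p: fibroblast and matrix (mean 1.02; 0.269), macrophage and monocyte (0.91; 0.281), neutrophil (1.33; 0.117), type I interferon (0.58; 0.314), interferon gamma response (0.76; 0.366), MHC class I (0.68; 0.269), immediate early and heat shock (0.83; 0.138), T cell (0.92; 0.187), cytotoxic (1.09; 0.269) and MHC class II (0.66; 0.526). The same held for midkine partners (0.47; 0.138), where Sdc3 was the only one of 11 to pass and 5 did adjusted over the list alone, blood endothelium (0.43; 0.429), hypoxia and glycolysis (0.37; 0.429), checkpoint (0.70; 0.169) and NK cell (1.37; 0.281). Members passing adjusted over the list alone numbered 9 of 18 fibroblast, 5 of 15 immediate early, 4 of 26 interferon gamma, 3 of 14 endothelial, 2 of 13 neutrophil and 1 of 21 macrophage genes. They numbered 1 each for type I interferon, checkpoint, NK cell and hypoxia genes, and 0 for MHC class I, MHC class II, T cell and cytotoxic genes. The matrix gene Col6a3 was at 572 ± 230 against 157 ± 82.7 (1.94 ± 0.44, adjusted p = 0.120), and Gzma at 73.8 ± 34.9 against 16.5 ± 11.3 (2.26 ± 0.72, adjusted p = 0.248). The stress list, not called, had a median of -0.17 and a mean of 0.01. The T cell call was lost without shMdk anti-PD1 tumour 1 (adjusted p = 0.115). MHC class II lost its call without IgG2a tumour 2 or anti-PD1 tumour 1 or 2 (0.341, 0.121 and 0.155). So did hypoxia without IgG2a tumour 2 or anti-PD1 tumour 1 or 4 (0.0596, 0.0814 and 0.0815), and endothelium without IgG2a tumour 2 or 3 or anti-PD1 tumour 1 (0.0684, 0.0757 and 0.154). Means ran down to 0.39 for MHC class II, 0.24 for endothelium, 0.49 for immediate early and 0.68 for fibroblast genes when a tumour was left out. The checkpoint call was lost without IgG2a tumour 1 or 2 or anti-PD1 tumour 1 (0.127, 0.0611 and 0.140). The NK call was lost without IgG2a tumour 1 or 2 or anti-PD1 tumour 1 or 2 (0.113, 0.106, 0.151 and 0.0857). Without the 2 libraries high in Gm42418 the checkpoint and NK calls ended (0.146 and 0.1097), and without the 5 with a positive GC slope the T cell, checkpoint and endothelium calls (0.106, 0.0595 and 0.0581).

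Whether anti-PD1 acted differently in the 2 lines was tested as a difference of effects, and 0 genes passed with limma (smallest adjusted p = 0.9998). At an unadjusted p under 0.05 there were 506 genes, against 733.6 expected with no effect. edgeR gave 0 genes (654 unadjusted) and DESeq2 0 (714 unadjusted). Sample weights and 2 surrogate variables also gave 0 (1559 and 1270 unadjusted). Without the 2 or the 5 libraries the count was also 0 (575 and 1383 unadjusted). Among the genes with the smallest p, the estimated anti-PD1 effect on Cd163, a scavenger receptor of macrophages, was 4.09 ± 0.95 log2 units above that in shCtrl tumours (SE; adjusted p = 0.9998). Its means were 1.16 ± 1.38 and 14.5 ± 7.62 reads in shMdk and 5.45 ± 2.85 and 1.83 ± 1.29 in shCtrl tumours (SD, n = 4; IgG2a, then anti-PD1). For Slfn4 the difference was 2.61 ± 0.62 and for Arg1 2.84 ± 0.84. Across genes the anti-PD1 effects in the 2 lines correlated at r = 0.30 (rho 0.365), with r between 0.116 and 0.442 when a tumour was left out (jackknife SD 0.349), and the comparisons shared no library.

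Lists called for a larger anti-PD1 effect in shMdk tumours numbered 14, all in that direction, with 0 members passing over all genes. With an estimated correlation 3 kept the call: alternatively activated myeloid (mean difference 1.88; adjusted p = 0.0188 with an estimated correlation; 6 of 12 adjusted over the list alone), NF-kB targets (0.53; adjusted p = 0.0188 with an estimated correlation) and dedifferentiated melanoma (0.90; adjusted p = 0.0468 with an estimated correlation; 2 of 15 adjusted over the list alone). The others, with that adjusted p in brackets, were fibroblast and matrix (1.45; 0.0936; 8 of 18 adjusted over the list alone), neutrophil (1.49; 0.0725), chemokines (1.19; 0.0725), blood endothelium (0.64; 0.281), immediate early (0.61; 0.242), midkine partners (0.32; 0.244), type I interferon (0.36; 0.674), macrophage (0.51; 0.674), lymphatic endothelium (0.99; 0.183), T cell (0.63; 0.391) and cytotoxic (0.70; 0.509). Examples were Chil3 (difference 3.66 ± 0.94), Tnc (2.40 ± 0.78), Col3a1 (2.86 ± 1.05), Cd40 (2.09 ± 0.76) and S100a8, a neutrophil calcium-binding protein (3.49 ± 1.48), none of which passed. The interferon gamma, MHC class I and MHC class II lists were not called (0.10, 0.07 and -0.19; adjusted p = 0.691, 0.846 and 0.464), and median, mean and test differed in sign for MHC class I and skeletal muscle.

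Several of these list differences rested on single tumours. The type I interferon call was lost without shCtrl IgG2a tumour 1, shCtrl anti-PD1 tumour 2 or shMdk anti-PD1 tumour 2 (adjusted p = 0.146, 0.508 and 0.165). T cell genes lost it without shCtrl IgG2a tumour 1, shCtrl anti-PD1 tumour 1, shMdk IgG2a tumour 2 or 4, or shMdk anti-PD1 tumour 1 or 2 (0.330, 0.168, 0.0647, 0.158, 0.511 and 0.495). Cytotoxic genes lost it without shCtrl IgG2a tumour 1, shCtrl anti-PD1 tumour 1 or 2, shMdk IgG2a tumour 1 or 2, or shMdk anti-PD1 tumour 1 (0.570, 0.191, 0.190, 0.0960, 0.144 and 0.165). The macrophage call ended without shCtrl IgG2a tumour 1 or 2, shCtrl anti-PD1 tumour 1 or 2, shMdk IgG2a tumour 2, or shMdk anti-PD1 tumour 1 or 2 (0.134, 0.163, 0.0507, 0.786, 0.191, 0.0762 and 0.0884). Immediate early genes lost the call without shMdk anti-PD1 tumour 4 (0.0758), lymphatic endothelium without shMdk IgG2a tumour 2 or shMdk anti-PD1 tumour 1 (0.0647 and 0.0942) and midkine partners without shCtrl IgG2a tumour 4 (0.0681). Leaving out the 2 libraries high in Gm42418 ended the type I interferon, cytotoxic and macrophage calls (0.950, 0.467 and 0.504), as did 2 surrogate variables (0.380, 0.137 and 0.254). Without the 5 libraries with a positive GC slope 6 lists were called. The neutrophil, NF-kB, endothelium, lymphatic endothelium, type I interferon and cytotoxic calls ended (0.245, 0.0525, 0.138, 0.155, 0.0525 and 0.530). The T cell and macrophage lists turned direction (adjusted p = 0.956 and 0.990).

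The size of several list differences also depended on single tumours. When a tumour was left out the mean ran from 0.05 to 0.78 for macrophage (0.51 with all tumours), 0.08 to 0.60 for type I interferon (0.36), 0.26 to 0.85 for T cell (0.63), 0.25 to 0.92 for cytotoxic (0.70), 0.28 to 0.80 for immediate early (0.61) and 0.19 to 0.41 for midkine partner genes (0.32). The lowest macrophage and type I interferon values came without shCtrl anti-PD1 tumour 2. Without the 2 libraries high in Gm42418 the mean was 0.16 for macrophage, 0.03 for type I interferon and 0.37 for cytotoxic genes, and with 2 surrogate variables 0.21, 0.12 and 0.50. Without the 5 libraries with a positive GC slope it was 0.05 for macrophage, -0.03 for T cell, 0.40 for cytotoxic and 0.79 for neutrophil genes (1.49 with all tumours).

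With camera, 6 lists were called in no comparison: melanocyte pigmentation, regulatory T cell, mitochondrially encoded, skeletal muscle, keratinocyte and erythroid genes. Melanocyte pigmentation genes had mean log2 differences of 0.17 and 0.14 for anti-PD1 in shCtrl and shMdk tumours, -0.16 and -0.18 for knockdown under IgG2a and anti-PD1, and -0.03 for the difference of effects. In the same order, regulatory T cell genes had 0.07, 0.36, 0.61, 0.90 and 0.29 (fry called them for knockdown under anti-PD1, adjusted p = 0.0140), and mitochondrially encoded genes -0.03, 0.08, -0.20, -0.09 and 0.11. Skeletal muscle genes had -0.17, 0.22, 0.29, 0.68 and 0.39, keratinocyte genes -0.42, -0.12, -0.03, 0.27 and 0.30, and erythroid genes -0.63, -0.23, -1.06, -0.65 and 0.40. Tyr, the rate-limiting enzyme of melanin synthesis, had -0.50 ± 0.32 and -0.46 ± 0.32 for the 2 knockdown comparisons (adjusted p = 0.732 and 0.501).

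**Figure D3:**
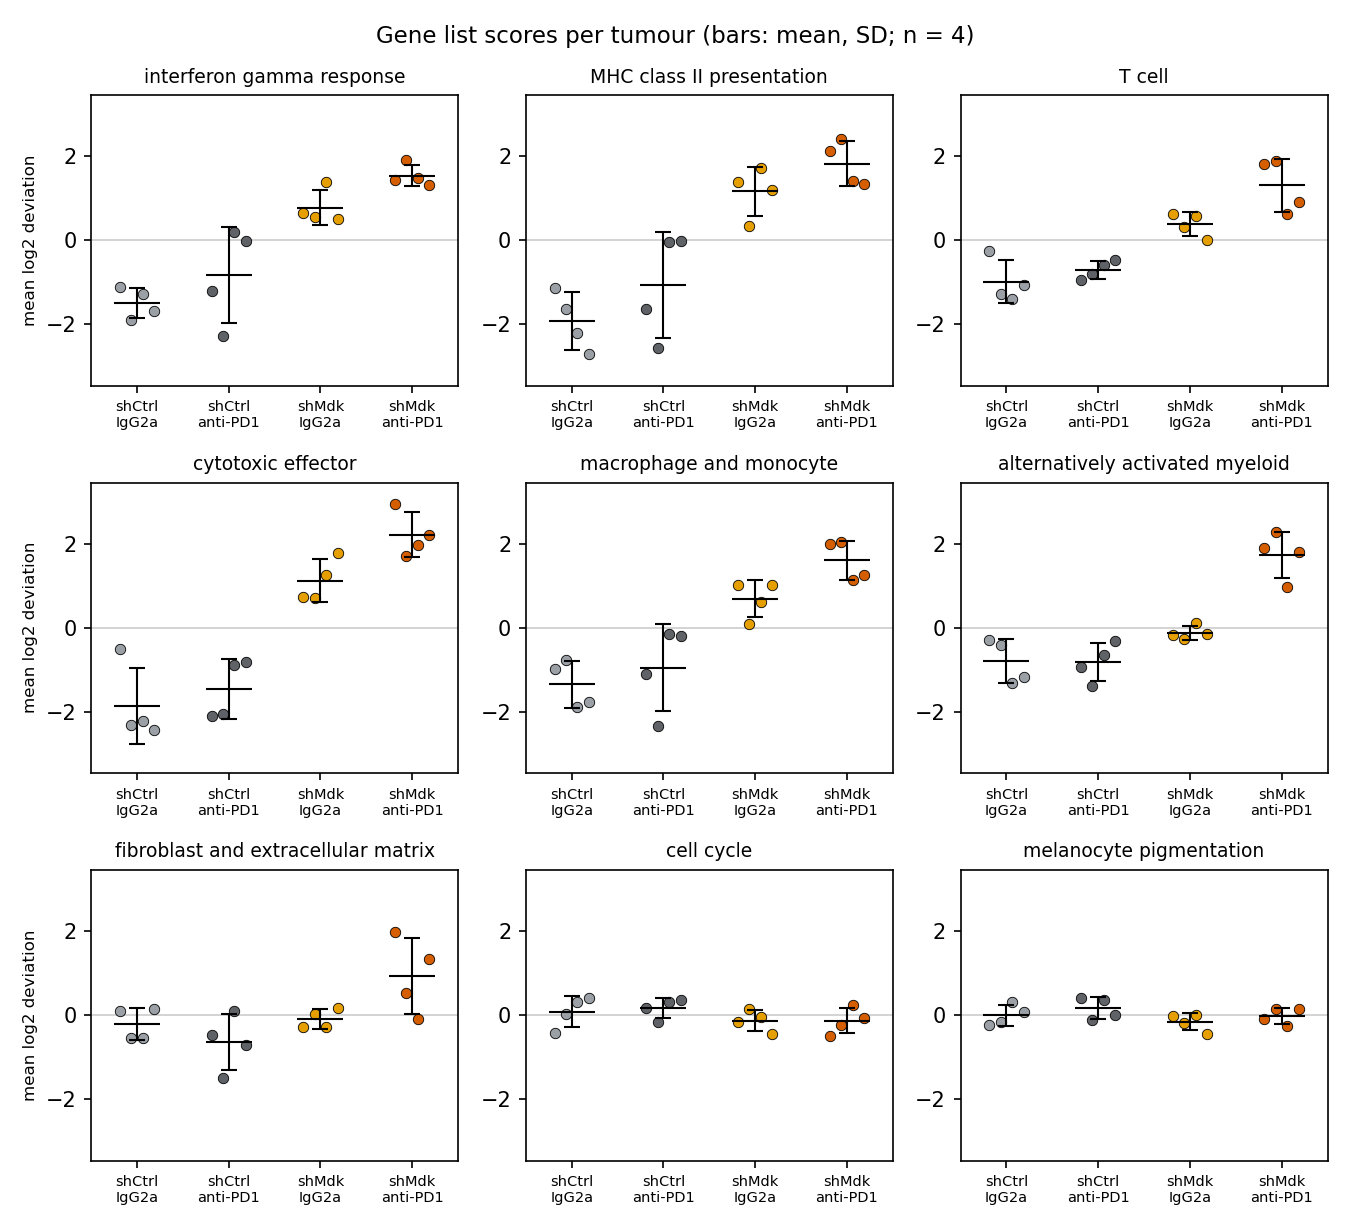
Gene list scores (vertical axes: mean log2 deviation of list members from their mean over all tumours) in each of the 16 tumours, by hairpin and antibody (horizontal axes), with bars for the mean and SD of 4 tumours, for 9 of the lists. MHC class II and cytotoxic scores are higher in shMdk tumours under both antibodies, and the alternatively activated myeloid score is highest in shMdk tumours under anti-PD1.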

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

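The tests of the GC trend, of Gm43305 and of the alternatively activated myeloid list, the surrogate variables, the removal of other tumours in equal numbers and the look at even splits were chosen after the data were seen. Among 140 groups of 4 tumours tested for a tumour far from the other 3, 6 were picked out, where chance alone picks out about 1 in 20 (7 here). They were 5686405 reads and 4.47% of reads on Gm42418 in shCtrl anti-PD1 tumour 2, 1.46% on Gm42418 in shCtrl IgG2a tumour 4, a cytotoxic score of -0.512 in shCtrl IgG2a tumour 1, an NF-kB score of -0.0113 in shMdk IgG2a tumour 2 and a midkine partner score of 0.174 in shCtrl anti-PD1 tumour 2.

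A difference of the anti-PD1 effect between shMdk and shCtrl tumours picked out 14 lists, tested as an interaction with camera. With an estimated correlation 3 of the 14 kept the call. Over all 14, the mean log2 differences were 1.88 for alternatively activated myeloid, 1.49 for neutrophil, 1.45 for fibroblast and matrix, 1.19 for chemokine, 0.99 for lymphatic endothelium, 0.90 for dedifferentiated melanoma, 0.70 for cytotoxic and 0.64 for blood endothelium genes. They were 0.63 for T cell, 0.61 for immediate early and heat shock, 0.53 for NF-kB, 0.51 for macrophage and monocyte, 0.36 for type I interferon and 0.32 for midkine partner genes. Several were smaller in other fits: without shCtrl anti-PD1 tumour 2, macrophage genes had 0.05 and type I interferon genes 0.08, and without the 2 libraries high in Gm42418 they had 0.16 and 0.03. T cell genes had 0.26 without shMdk anti-PD1 tumour 2 and cytotoxic genes 0.25 without shCtrl IgG2a tumour 1. As many lists or more were called in 16 of 100 splits of the tumours (real value 14, highest other 22). For genes the real value was 0 and the highest other 1283, so 100 of 100 splits gave as many by construction and the count says nothing about chance.

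Other splits of the same 8 tumours into 4 and 4 set the scale for chance, with 35 splits per comparison, the real one included. For knockdown under anti-PD1, as many genes or more passed in 1 of 35 splits (real value 870, highest other 2), and for anti-PD1 in shMdk tumours in 1 of 35 (real value 5, highest other 3). For knockdown under IgG2a it was 2 of 35 (real value 255, highest other 2420). For anti-PD1 in shCtrl tumours the real value of 0 (highest other 1) made it 35 of 35 by construction. Gene lists were called as often or more in 5 of 35 splits for knockdown under anti-PD1 (real value 21, highest other 24), in 4 of 35 for knockdown under IgG2a (real value 16, highest other 16), in 3 of 35 for anti-PD1 in shMdk tumours (real value 19, highest other 19) and in 14 of 35 for anti-PD1 in shCtrl tumours (real value 8, highest other 15). In the first 3 of these comparisons, every other split that reached the real count kept 3 of the 4 tumours of a group together and so held part of the real contrast. The 18 even splits, with 2 tumours of each group on each side, gave at most 16, 8 and 14 lists there. For anti-PD1 in shCtrl tumours even splits gave up to 15 lists. With 2 surrogate variables, as many genes or more passed for anti-PD1 in shMdk tumours in 1 of 35 splits (real value 287, highest other 185).

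The split with 2420 genes set shCtrl IgG2a tumours 1 and 2 with shMdk IgG2a tumours 3 and 4 against the others, which are the 4 IgG2a tumours with a positive GC slope. In the 5 libraries with such a slope, genes with 9% to 30% GC in the 3′ end lay 0.18 log2 units below their mean in the tumour's own group. Genes with 46% to 74% GC lay 0.13 above it. The libraries were chosen by that slope, so the direction of both shifts follows from the choice and only their size is informative. Where a group held several such libraries, its mean took up part of the shift. Within groups, the first component held 48.1% of the variance, and its loadings followed 3′ GC content (Spearman rho 0.444 across genes), which is consistent with a bias in library preparation or in RNA quality. The sign of the loadings was set to follow the slope, so only the size of rho is informative. The widest range of the slope inside a group was 93.2% of its range over all tumours. The slope therefore varied among tumours given the same hairpin and antibody. That range cannot exclude a link with the antibody. Of the 5 libraries, 4 came from IgG2a tumours and 1 from an anti-PD1 tumour (shMdk tumour 1). The anti-PD1 comparisons therefore set groups with unequal slopes against each other. RNA integrity per tumour was not analysed here, and whether a biological difference between tumours follows GC content was not tested.

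Gm43305 was high in every shMdk tumour, with the lowest shMdk value 23.01-fold above the highest shCtrl value. RNA of T cells did not account for this, since Gm43305 fell by 0.931 log2 units with anti-PD1 in shMdk tumours (exact p = 0.0286) while the T cell score was 0.92 higher (exact p = 0.0571). A change of the whole region did not account for the high values. The 13 other tested genes within 300 kb had a median log2 fold change of -0.28 ± 0.24 (SE), with 0 passing under both antibodies. A difference between the 2 tumour lines that does not come from the Mdk level, such as the site of hairpin insertion, cannot be told apart from the knockdown (23.01-fold), because each line carried 1 hairpin.

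The alternatively activated myeloid list was higher with anti-PD1 in shMdk tumours. The list score minus the macrophage score was 0.939 higher under anti-PD1 (-0.81 ± 0.44 against 0.13 ± 0.33, SD, n = 4; exact p = 0.0286). This cannot exclude more macrophages and monocytes as the source, since members of the 2 lists need not scale alike with cell number. The average GC trend did not account for the rise of the list, since the mean log2 fold change was 1.82 after the GC correction (camera adjusted p = 3.40e-11). It was 1.90 without the 5 libraries (camera adjusted p = 2.18e-07), against 1.85 with all tumours. The correction removes only the average trend of each library, and single genes could differ far more. A part of the rise that goes with these libraries in other ways is therefore not excluded by the correction. More macrophages and monocytes, a change in the state of myeloid cells, or an influx of cells that express these genes may remain as hypotheses, found and tested on the same tumours.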

How the results depend on the processing

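The settings with surrogate variables, GC correction and removal of 2 or 5 libraries were chosen after the data were seen, and the others were planned. Mdk was lower with knockdown in every setting, at -2.43 to -1.96 under IgG2a and -2.41 to -1.85 (log2) under anti-PD1 when a tumour was left out. For anti-PD1 in shCtrl tumours (0 genes), sample weights gave 20, DESeq2 7, 2 surrogate variables 2 and removal of the 2 libraries high in Gm42418 3. For anti-PD1 in shMdk tumours (5 genes), a pseudocount of 0.5 gave 3 and of 5 gave 27, no filter 3, TMM factors 3, sample weights 73, edgeR 8, DESeq2 248, 2 groups only 25, surrogate variables 287, GC correction 2, and removal of the 2 or the 5 libraries 11 or 1. Knockdown under IgG2a (255) gave 983 with sample weights, 449 with DESeq2, 704 with surrogate variables and 74 without the 5 libraries. Knockdown under anti-PD1 (870) gave 1889, 1310 and 2526 with sample weights, DESeq2 and surrogate variables. The share of higher genes was 93.7% under IgG2a and 83.2% under anti-PD1, 77.8% and 58.0% with surrogate variables, and 66.0% and 63.3% with sample weights. Without the 5 libraries it was 63.5% and 78.9%. The difference of anti-PD1 effects stayed at 0 genes in every setting described with the methods. Removing as many tumours per group as the 5 libraries, in 143 other ways, gave 0 genes in 142. The highest count there was 190, without shCtrl IgG2a tumours 1 and 2, shMdk IgG2a tumours 1 and 2, and shMdk anti-PD1 tumour 1. Leaving out each tumour in turn gave 0 to 2, 0 to 12, 136 to 271, 443 to 858 and 0 to 0 genes for these 5 comparisons in that order.

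Lists called for anti-PD1 in shCtrl tumours (8) numbered 0 with an estimated correlation, 0 with fry, 16 with surrogate variables, 14 without the 2 libraries and 14 without the 5, and 1 to 15 without each tumour. For anti-PD1 in shMdk tumours (19) they numbered 4 with an estimated correlation, 8 with fry and 13 to 22 without each tumour. Knockdown under IgG2a (16) gave 10 with an estimated correlation and 15 to 17 without each tumour, and knockdown under anti-PD1 (21) gave 14 with an estimated correlation and 21 to 23 without each tumour. The interaction (14) gave 3 with an estimated correlation, 2 with fry, 6 without the 5 libraries and 10 to 17 without each tumour. Direction turned for type I interferon with anti-PD1 in shCtrl tumours (-0.0275 to 0.49 without each tumour), and without the 5 libraries for the T cell (-0.0349) and macrophage (mean 0.0463, with a test direction of lower) interaction. Surrogate variables ended the type I interferon, cytotoxic and macrophage interaction calls (adjusted p = 0.380, 0.137 and 0.254) and the fibroblast call for anti-PD1 in shCtrl tumours (0.119). Quantile normalisation ended the type I interferon, stress and adipocyte calls there (0.0597, 0.115 and 0.0640) and the dendritic cell and stress calls for knockdown under IgG2a (0.0673 and 0.161), and the GC correction the stress call in shCtrl tumours (0.0572). The correlation of anti-PD1 effects between lines (0.30, jackknife SD 0.349) was 0.116 to 0.442 without each tumour, 0.484 with the filter at a mean of 20, 0.489 over the 5 genes passing in either line and 0.225 with surrogate variables. No paired analysis was possible because replicate numbers were given in accession order and mark no shared animal, day or batch. The cause of these changes was not tested. Where tumours were removed, smaller groups could not be told apart from the changed make-up of the groups. With 4 tumours per group, and T cell genes such as Cd8a at 1.02 to 12.1 mean reads, small differences in rare cells were out of reach.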

Other observations

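Ighg2c, an antibody heavy-chain gene, had means of 1.29 and 2.44 normalised reads in shCtrl tumours under IgG2a and anti-PD1, and 59.7 and 8.10 in shMdk tumours. Its anti-PD1 effect was lower in shMdk tumours by 3.50 ± 0.79 log2 units (limma adjusted p = 0.9998), so the difference did not pass. Ubd, a ubiquitin-like protein induced by interferon gamma, rose with knockdown by 5.04 ± 0.58 log2 units under anti-PD1 (adjusted p = 1.61e-04).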
